A study of Gossypium hirsutum with 18 samples.

How the data were processed

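Poly-A RNA of upland cotton, Gossypium hirsutum, sampled on day 10, was sequenced in 18 libraries, 3 for each combination of 2 lines (Coker 312 glanded and glandless) and 3 organs (leaf, stem and root, the last labelled as the lower root). The deposited values were counts of reads per gene, which the authors made with HISAT2 2.0.5 for alignment and featureCounts 1.5.0-p3 for counting, per the submitters' processing notes. The deposited FPKM values were computed by the authors from the same counts with a library size of 0.773 to 1.20 times the count total, as the values show. The genome build and the handling of reads that match several genes are not given in the sources used here. Upland cotton is tetraploid, so counts of homoeologs, of near-identical paralogs such as cadinene synthases, and of overlapping or antisense genes are uncertain as to which copy gave the reads.

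The table held 100911 genes. Of these, 99451 matched the RefSeq gene table of assembly Gossypium_hirsutum_v2.1 by identifier, and 99.7% of those had the same start and end. Start and end are as in the deposited table, and chromosome names A01 to D13 came from that match. A further 1458 were gene models of the authors without a RefSeq entry. Total counts ranged from 16729047 to 21634501 per library, and the biological coefficient of variation was 0.0749. Replicates differed by more than sampling noise (chi-square per degree of freedom of 1.79 to 4.83), so none was counted as a repeat. The labels do not say that the 3 libraries of a group came from separate plants, so p-values measure only the spread between these samples, which may be technical.

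Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, glmQLFit and glmQLFTest) in R 4.3.3, with all 18 libraries in one fit of 6 group means, filterByExpr, TMM scaling and Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. Fold changes are glandless minus glanded on the log2 scale, and levels are TMM-scaled CPM, given as mean ± SD of 3 libraries. A gene with no counts in one group has a lower bound on its fold, taken at 3 counts over the group. With 1 to 3 counts the ratio has a 95% counting interval. Bounds and intervals cover counting error only. Differences between organs averaged over lines, and the difference of the line effect between organs, were contrasts of the same fit. A gene was organ-enriched when called and at least 2-fold higher than in both other organs.

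Gene lists were fixed by patterns in gene descriptions, 26 in all: gossypol enzymes, mevalonate pathway, plastid methylerythritol phosphate pathway, other terpene synthases, dirigent proteins, jasmonate genes, MYC-type bHLH factors, lignin, flavonoid, photosynthesis, secondary wall, endodermis, root hair, cytosolic ribosomal proteins, heat shock, pathogenesis-related, glutathione S-transferases, lipid transfer and cuticle, ABC and MATE transporters, cyclins and histones, aquaporins, WRKY, ethylene-responsive factors, late embryogenesis abundant proteins, cytochrome P450 and the dioxygenase group. Photosynthesis, secondary wall, endodermis, root hair, cuticle and histone lists also served as markers of cell types whose share of a sample could differ. Lists were tested with camera (limma 3.58.1, preset correlation 0.01). With a correlation estimated per list, 5 of 7 calls in leaf, 14 of 20 in stem and 11 of 15 in root held, and the p of each of the others stands beside its count. Cytochrome P450 enzymes in stem passed with it and not with the preset value. Chromosomes were tested with one-sided Fisher's exact tests.

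Named genes followed a rule: for each organ, the 5 largest rises and falls among called, described genes with a mean count of at least 50 in the higher group and no overlap of libraries; for each list past the threshold, the 2 members with the smallest p in its direction; the best expressed member of each enzyme class of the gossypol route and of MYC2 on A12 and D12; the 10 described genes called in all 3 organs with the smallest largest adjusted p; and 5 described organ-enriched genes per organ. Of the genes called in all 3 organs, 1 that the rule named is not reported here. Descriptions held no CYP706B or CYP71BE gene. The list called gossypol enzymes held 19 cadinene synthases, 25 CYP82D genes and 13 CYP736A genes. The P450 genes were matched by family name, so a role of each in gossypol synthesis is not shown. The design, the lists, this rule and the alternatives were fixed before the data were examined, apart from 1 alternative, the test of annotated gene families and most tests of explanations.

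The method was tested on simulated counts of 57364 genes drawn from the real means over all libraries, so groups differed only by planted changes. Of planted changes of 1.5-fold, 2-fold and 4-fold, it recovered 52.2%, 83.6% and 98.5% in leaf, 67.2%, 83.6% and 100% in stem, and 53.7%, 80.6% and 98.5% in root. False calls were 3.77%, 6.19% and 5.50% of calls. Only 378, 230 and 430 genes were changed between lines in leaf, stem and root, against 24242, 25963 and 18042 called in the data. Recovery, false calls and scaling were thus not tested with as many changed genes as in the real data. The planted photosynthesis list in leaf and the planted D05 in root passed, and a planted share of 8% glandless root counts was estimated at 7.79%. Alternatives were DESeq2 1.42.0, its size factors, library totals, other count filters and thresholds, each organ fitted alone, replicate blocks, limma on log2(FPKM + 1), list tests with an estimated correlation or fry, and leaving out each library. DESeq2 gave no adjusted p for 4 genes in each comparison, which stayed out of its counts.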

Results

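Gene expression was measured by poly-A RNA sequencing in upland cotton (Gossypium hirsutum), in the background Coker 312, a cultivar used widely for transformation. A glanded line was set against a glandless line. Pigment glands are the cavities in which cotton stores gossypol and related terpenoid aldehydes. Leaf, stem and root were sampled on day 10, with 3 libraries for each of the 6 combinations of line and organ, 18 libraries in all. The total count per library ranged from 16729047 to 21634501, and 59600 genes were tested. The first principal component of log2 CPM held 69.7% of the variance and the second 20.2%, and the organs parted along both. A further 4.4% fell on the third component, which placed all 9 glanded libraries above all 9 glandless libraries.

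**Figure D1:**
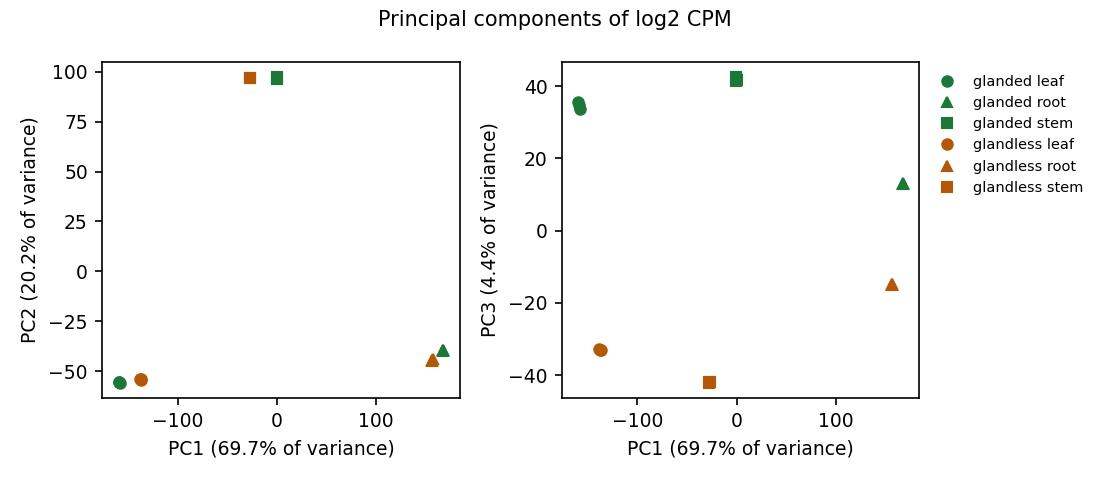
Principal components of log2 CPM over the tested genes in the 18 libraries, with component 1 on the horizontal axis and component 2 or 3 on the vertical axis. Each point is a library, shape gives the organ and colour the line; the organs part on components 1 and 2, and the lines part on component 3.

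The first comparison asked how leaf expression differed between the lines. Genes of photosynthesis were lower in glandless leaf: 133 of 148 members fell and 1 rose (135 and 1 adjusted over the list alone, median log2 fold change -0.99, camera adjusted p = 1.21e-70). Among chlorophyll a-b binding proteins, which hold the antenna pigments, 39 of 44 fell, with a median log2 fold change of -2.03. The antenna gene CP26, LOC107914060 (chromosome D05, 23967442 to 23969633), stood at 386 ± 21.2 CPM in glandless and 1920 ± 120 CPM in glanded libraries (log2 fold change -2.31 ± 0.054 (SE), edgeR adjusted p = 1.38e-34, n = 3 per line), and chlorophyll a-b binding protein 151, LOC107954741, changed by -2.55 ± 0.059. The list of gossypol enzymes did not pass in leaf, where 14 of 57 members fell and 11 rose (14 and 11 adjusted over the list alone, median log2 fold change 0, camera adjusted p = 0.405), and its mean of 0.44 had the opposite sign to the test. With library totals it passed as lower (adjusted p = 0.0352), and its summed level was 504 to 519 CPM in glandless and 719 to 739 CPM in glanded leaf libraries. The parts of the list differed, as 6 of 19 cadinene synthases rose and 0 fell (median log2 fold change 0.13). Among the 38 other members, P450 genes matched by family name, 14 fell and 5 rose (median -0.15). The best expressed cadinene synthase, which makes the first committed sesquiterpene of the gossypol route, LOC107920688 (chromosome A04, 4145368 to 4148387), had 0.486 ± 0.304 CPM in glandless and 0.455 ± 0.252 CPM in glanded libraries (edgeR adjusted p = 0.864). CYP736A12 LOC107892025 changed in leaf by -0.84 (log2, edgeR adjusted p = 3.02e-05), and CYP82D47 LOC107944158 by 0.88 (edgeR adjusted p = 0.0228), a call lost without glanded leaf replicate 2 (0.35, adjusted p = 0.359) or glandless leaf replicates 1 (0.63, 0.166) or 3 (0.85, 0.0569). Genes enriched in leaf fell in leaf, 3756 of 8769 against 1136 that rose, with a median log2 fold change of -0.25 that became 0.069 with library totals, where the median of all genes was 0.33. The calls for these genes then became 2252 lower and 2518 higher.

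Several genes had 0 or 1 count in the leaf of one line. The cytochrome P450 CYP736A12 LOC107913466 (chromosome A13, 2738139 to 2742293) reached 67.6 ± 2.3 CPM in glandless and 0 CPM in glanded libraries, at least 1070-fold higher. Of the other leading rises, a disease resistance protein of the RUN1 type, LOC107935470, had 30.3 ± 1.76 CPM in glandless and 0 CPM in glanded libraries, the receptor-like proteins LOC121220185 and LOC121220187 were at least 386-fold and 318-fold higher, and the P450 71A1-like gene LOC107950200 was at least 307-fold higher. In the other direction, TIC236, LOC107922603 (chromosome D01, 23866269 to 23871329), a part of the chloroplast import machinery, was at least 578-fold lower at 0 CPM in glandless and 30.3 ± 3.33 CPM in glanded libraries. An Xa21-type receptor kinase, LOC107903669, was at least 362-fold lower, the splicing factor LOC107934420 at least 221-fold lower and an RNA polymerase subunit, LOC121211417, at least 209-fold lower. The UDP-glycosyltransferase 75C1-like gene LOC107942101 fell 2100-fold, with a counting interval of 377 to 83100, since its glandless total was 1 count.

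Other fixed groups moved in leaf as well. Gene values with ± and no unit are log2 fold changes with their SE, n = 3 per line. In the cytosolic mevalonate pathway, which supplies farnesyl diphosphate, 26 of 45 members rose and 4 fell (26 and 4 adjusted over the list alone, median log2 fold change 0.46, camera adjusted p = 0.00125), while the summed level was 683 CPM in glandless and 695 CPM in glanded leaf. Mevalonate kinase LOC107930932 rose by 2.52 ± 0.15 on the log2 scale and an HMG-CoA reductase, LOC107898896, by 1.35 ± 0.12, but the best expressed HMG-CoA reductase, LOC107939227, fell (-2.38 ± 0.058). For the plastid methylerythritol phosphate pathway, 18 of 40 members fell and 4 rose (18 and 4 adjusted over the list alone, median log2 fold change -0.15, camera adjusted p = 0.00993). Deoxyxylulose phosphate synthase LOC107897631 stood at -0.95 ± 0.07 and geranylgeranyl diphosphate synthase LOC107896517 at -1.03 ± 0.079. Among secondary wall genes, 36 of 120 members fell and 8 rose (36 and 8 adjusted over the list alone, median log2 fold change -0.27 or -0.23 with bounded values, camera adjusted p = 0.00364). The fasciclin-like arabinogalactan proteins LOC107954983 (-2.74 ± 0.063) and LOC107889457 (-2.62 ± 0.066) had the smallest p in that direction. Most of the falls came from this class, where 23 of 40 members fell and 2 rose (median -0.61). Among the 80 other members 13 fell and 6 rose (median 0), so the fall did not extend to the list at large. In the heat shock list 59 of 162 members rose and 23 fell (61 and 23 adjusted over the list alone, median log2 fold change 0.16 or 0.14 with bounded values, camera adjusted p = 0.00757). Of its members, 35 of 162 were not named as heat shock proteins or chaperones, and both leading genes, LOC107907538 (1.29 ± 0.09) and LOC121217457 (1.99 ± 0.14), were proline-rich proteins, while 50 of the 127 named heat shock proteins or chaperones rose and 13 fell. Among cytosolic ribosomal proteins 321 of 709 members rose and 36 fell (327 and 37 adjusted over the list alone, median log2 fold change 0.27, camera adjusted p = 5.58e-06, adjusted p = 0.338 with an estimated correlation). The leading members were LOC107909701, at least 188-fold higher, and LOC107896471 (1.04 ± 0.10). For aquaporins, 38 of 88 members fell and 25 rose (38 and 26 adjusted over the list alone, median log2 fold change -0.14 or -0.045 with bounded values, camera adjusted p = 0.00125, adjusted p = 0.338 with an estimated correlation). PIP2-2 LOC107889604 stood at -5.28 ± 0.094 and PIP2-1 LOC107891130 at -3.60 ± 0.11.

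Some lists did not pass in leaf, each given with its median log2 fold change and camera adjusted p. Other terpene synthases (0, 0.852), dirigent proteins (0, 0.968), jasmonate genes (0.05, 0.401), MYC-type factors (-0.14, 0.188) and lignin genes (0, 0.319) were among these. Flavonoid genes (0.14, 0.0698), endodermis genes (0, 0.264), the root hair list (0.05, 0.642), pathogenesis-related proteins (0.068, 0.477) and glutathione S-transferases (0.26, 0.0554) were among these. Lipid transfer and cuticle genes (0, 0.478), ABC and MATE transporters (0, 0.524), cyclins and histones (0.093, 0.357), WRKY genes (0.20, 0.852) and ethylene-responsive factors (0, 0.0572) were among these. Late embryogenesis abundant proteins (-0.30, 0.357), cytochrome P450 enzymes (0, 0.357) and the dioxygenase group (0, 0.482) were among these. With each organ fitted alone, ethylene-responsive factors (adjusted p = 0.000362), flavonoid genes (0.0103) and late embryogenesis abundant proteins (0.00876) passed in leaf, as did glutathione S-transferases with the replicate block (0.0483). Test and mean differed in sign for dirigent proteins (mean -0.033), flavonoid genes (-0.079), cuticle genes (0.33) and transporters (0.05). Both median and mean differed in sign from the test for the root hair list, tested as lower, and for late embryogenesis abundant proteins, tested as higher. In all, edgeR called 24242 genes in leaf, 12135 higher and 12107 lower in glandless, of which 4562 and 4272 changed at least 2-fold. Scaling by library totals instead of TMM moved the median of all genes to 0.33 (log2) and the calls to 24905 higher and 6750 lower, and under it the median of the methylerythritol phosphate list became 0.048, that of aquaporins 0.021 and that of secondary wall genes 0. The counts of these lists then became 13 lower and 13 higher, 30 lower and 34 higher, and 23 lower and 21 higher. Photosynthesis genes took 7.68% ± 0.135 of glanded and 5.13% ± 0.117 of glandless leaf counts (SD, n = 3).

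**Figure D2:**
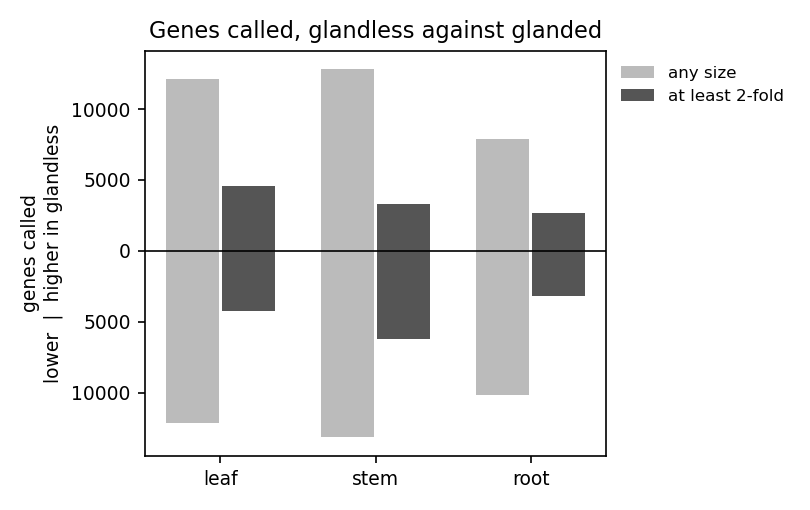
Number of genes called by edgeR at an adjusted p under 0.05 in each organ, above 0 for genes higher and below 0 for genes lower in glandless plants. Grey bars count changes of any size and dark bars those of at least 2-fold; in stem 6195 genes fell and 3303 rose at least 2-fold.

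The same comparison was made in stem, where gossypol enzymes fell: 39 of 57 members fell and 5 rose (39 and 5 adjusted over the list alone, median log2 fold change -4.47 or -4.0 with bounded values, camera adjusted p = 3.56e-19). Of 19 cadinene synthases 17 fell, among them LOC107920688 at 0.27 ± 0.155 CPM in glandless and 34.8 ± 3.1 CPM in glanded libraries (log2 fold change -6.97 ± 0.17 (SE), edgeR adjusted p = 1.87e-34, n = 3 per line). The P450 enzymes CYP82D47 LOC107944158 (chromosome A05, 19640543 to 19642455) and CYP736A12 LOC107892025 (chromosome D09, 24950785 to 24956038), of families with known members in gossypol synthesis, changed by -6.86 ± 0.19 and -7.34 ± 0.15, and the CYP736A12 gene on A09, LOC107937536, by -6.61 ± 0.14. Among all 25 CYP82D genes of the list 16 fell and 2 rose, and among the 13 CYP736A genes 6 fell and 3 rose. In the mevalonate pathway upstream, 29 of 45 members fell and 5 rose (30 and 7 adjusted over the list alone, median log2 fold change -0.57, camera adjusted p = 2.28e-07). HMG-CoA reductase LOC107939227 stood at -1.73 ± 0.057, HMG-CoA synthase LOC107946991 at -2.21 ± 0.10 and farnesyl diphosphate synthase LOC107905701 at -0.85 ± 0.066. Genes enriched in root also fell in stem, 3543 of 8709 against 768 that rose, with a median log2 fold change of -0.63, and 38 of the 57 gossypol enzymes belonged to that root-enriched set. So did 42 of 85 jasmonate genes, 98 of 202 WRKY genes, 120 of 298 ethylene-responsive factors and 42 of 100 glutathione S-transferases. Dirigent proteins (46 of 71) and the dioxygenase group (95 of 153) shared this, but pathogenesis-related proteins (37 of 232) and secondary wall genes (20 of 120) did not. Whether any of these lists fell beyond other root-enriched genes was not tested.

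Jasmonate genes fell with them, as 51 of 85 members fell and 7 rose (54 and 7 adjusted over the list alone, median log2 fold change -0.89 or -0.83 with bounded values, camera adjusted p = 1.06e-16). TIFY proteins, the repressors of jasmonate signalling, made up 26 of these falls out of 35 members, with TIFY 11B LOC107916413 (chromosome D10, 5580590 to 5582594) at 8.76 ± 0.864 CPM in glandless and 125 ± 2.05 CPM in glanded libraries and the lipoxygenase LOC107915240 at -3.61 ± 0.081. For WRKY transcription factors, 113 of 202 members fell and 31 rose (115 and 34 adjusted over the list alone, median log2 fold change -0.98 or -0.86 with bounded values, camera adjusted p = 1.26e-09). WRKY18-like LOC121203008 changed by -8.90 ± 0.17, and the WRKY18-like gene on A07, LOC107953740, fell 5030-fold, with a counting interval of 903 to 199000. Ethylene-responsive factors included RAP2-type genes LOC107926521 (-2.05 ± 0.068) and LOC107940910 (-2.83 ± 0.11), and 128 of 298 members fell and 65 rose (136 and 67 adjusted over the list alone, median log2 fold change -0.29 or -0.26 with bounded values, camera adjusted p = 0.0198, adjusted p = 0.0626 with an estimated correlation). Pathogenesis-related proteins were lower too, since 85 of 232 members fell and 27 rose (85 and 28 adjusted over the list alone, median log2 fold change -0.29 or -0.23 with bounded values, camera adjusted p = 0.000917). The allergen-type gene LOC107908518 stood at -7.72 ± 0.16 and LOC107898953 at -6.43 ± 0.13. In glutathione S-transferases 50 of 100 members fell and 13 rose (50 and 13 adjusted over the list alone, median log2 fold change -0.32 or -0.28 with bounded values, camera adjusted p = 3.28e-05). LOC107891002 stood at -4.28 ± 0.081 and LOC107889738 at -6.92 ± 0.15.

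Phenolic and terpenoid groups followed. For lignin and phenylpropanoid genes 90 of 221 members fell and 51 rose (93 and 54 adjusted over the list alone, median log2 fold change -0.091 or -0.075 with bounded values, camera adjusted p = 0.00529). Laccase-14 LOC107959545, which fell 510-fold, with a counting interval of 174 to 2480, and LOC107914066, which fell 996-fold, with a counting interval of 178 to 39400, had the smallest p in that direction. Flavonoid genes gave the count that 44 of 84 members fell and 11 rose (44 and 12 adjusted over the list alone, median log2 fold change -0.68, camera adjusted p = 8.65e-09). Flavonoid 3'-monooxygenase LOC107963672 stood at -7.27 ± 0.20 and chalcone synthase LOC107927759 at -1.63 ± 0.057. In dirigent proteins, which direct phenoxy radical coupling, 29 of 71 members fell and 3 rose (29 and 3 adjusted over the list alone, median log2 fold change -0.56 or -0.29 with bounded values, camera adjusted p = 9.48e-05). LOC107903450 stood at -6.30 ± 0.16 and LOC107903448 fell 173-fold, with a counting interval of 59 to 844. Among terpene synthases outside the cadinene class 10 of 17 members fell and 0 rose (10 and 0 adjusted over the list alone, median log2 fold change -3.53 or -2.11 with bounded values, camera adjusted p = 0.000174). Terpene synthase 10-like LOC107939025 (chromosome D09, 2078688 to 2082892) was at least 530-fold lower, and germacrene D synthase-like LOC107916720 fell 1210-fold, with a counting interval of 216 to 47800. For the plastid methylerythritol phosphate pathway 20 of 40 members fell and 5 rose (21 and 5 adjusted over the list alone, median log2 fold change -0.26, camera adjusted p = 0.00108). LOC107918523 stood at -6.23 ± 0.26 and LOC107926260 was at least 188-fold lower. Dioxygenases, short-chain dehydrogenases and glyoxalases of the kinds used in gossypol synthesis gave the result that 62 of 153 members fell and 18 rose (63 and 18 adjusted over the list alone, median log2 fold change -0.50 or -0.11 with bounded values, camera adjusted p = 9.74e-07). LOC107942044 stood at -6.76 ± 0.11 and LOC121212611 at -6.97 ± 0.14.

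Wall, water channel, transport and stress lists also passed in stem. In the secondary wall list 48 of 120 members fell and 19 rose (48 and 20 adjusted over the list alone, median log2 fold change -0.16, camera adjusted p = 0.00126). Arabinogalactan proteins LOC107946184 (-1.62 ± 0.075) and LOC107889975 (-1.31 ± 0.06) had the smallest p in that direction. Of the 40 fasciclin-like arabinogalactan proteins 28 fell and 2 rose in stem (median -0.29). The 80 other members went both ways there, 20 lower and 17 higher (median -0.0008). The root hair list held 30 proline-rich receptor kinases among 47 members and 21 of 47 members fell and 2 rose (21 and 2 adjusted over the list alone, median log2 fold change -0.38 or -0.32 with bounded values, camera adjusted p = 0.00139). The kinases LOC107938246 (-2.07 ± 0.077) and LOC107946476 (-1.88 ± 0.082) had the smallest p in that direction. For aquaporins 58 of 88 members fell and 14 rose (59 and 15 adjusted over the list alone, median log2 fold change -0.48 or -0.47 with bounded values, camera adjusted p = 9.37e-09, adjusted p = 0.0639 with an estimated correlation). TIP1-2 LOC107950283 stood at -3.56 ± 0.083 and PIP2-2 LOC107889604 at -2.72 ± 0.074. In ABC and MATE transporters 115 of 349 members fell and 56 rose (116 and 56 adjusted over the list alone, median log2 fold change -0.15 or -0.14 with bounded values, camera adjusted p = 0.0191, adjusted p = 0.0639 with an estimated correlation). LOC107897348 (-3.18 ± 0.087) and LOC107940004 (-2.71 ± 0.083) had the smallest p in that direction. Late embryogenesis abundant proteins and dehydrins included LOC121203613 (-3.67 ± 0.16) and LOC107922715 (-1.96 ± 0.11), and 15 of 26 members fell and 3 rose (15 and 4 adjusted over the list alone, median log2 fold change -0.82, camera adjusted p = 0.00563, adjusted p = 0.139 with an estimated correlation). Their summed level ran the other way, at 719 CPM in glandless and 542 CPM in glanded stem. The heat shock list was led by the proline-rich proteins LOC107907538 (-1.69 ± 0.069) and LOC121232133 (-1.20 ± 0.067), and 54 of 162 members fell and 23 rose (54 and 23 adjusted over the list alone, median log2 fold change -0.17, camera adjusted p = 0.0458, adjusted p = 0.0616 with an estimated correlation). That call was lost without glanded stem replicate 1 (adjusted p = 0.054) or 3 (0.068), and the summed levels of the lines overlapped between libraries. Cyclins and histones were the group that rose, where 58 of 195 members rose and 9 fell (54 and 8 adjusted over the list alone, median log2 fold change 0.25, camera adjusted p = 0.00194, adjusted p = 0.185 with an estimated correlation). The H1-like histones LOC107912798 (1.63 ± 0.071) and LOC107913009 (1.33 ± 0.083) had the smallest p in that direction. Some lists did not pass in stem, each given with its median log2 fold change and camera adjusted p. MYC-type factors (-0.30, 0.056), photosynthesis genes (0.0097, 0.946), endodermis genes (0, 0.305), ribosomal proteins (0.011, 0.242), lipid transfer and cuticle genes (-0.23, 0.377) and cytochrome P450 enzymes (-0.072, 0.0844) were among these. MYC-type factors passed in stem with the replicate block (adjusted p = 0.0423), without the filter (0.0211) and with limma (0.0363). Photosynthesis genes had a mean of -0.04 in stem and were tested as lower, opposite in sign to the median. Cytochrome P450 enzymes passed as lower in stem with an estimated correlation (adjusted p = 0.00795), with library totals (0.0261) and with each organ fitted alone (0.03).

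Single genes again parted the lines in stem. The dioxygenase LOC121225257 (chromosome D13, 61910640 to 61912513) was at least 1040-fold lower, the resistance protein RPV1 LOC107932362 at least 412-fold and glutathione S-transferase F12-like LOC107899373 at least 394-fold lower. Higher in glandless stem were the resistance protein LOC107902249 (at least 286-fold), the ribosomal protein LOC107909701 (at least 203-fold), the aminotransferase LOC107956040 (at least 200-fold), CYP736A12 LOC107913466 (at least 132-fold) and ferrochelatase LOC107956740 (at least 126-fold). In all, 25963 genes were called, 12815 higher and 13148 lower, with 3303 and 6195 at 2-fold or more. Scaling by library totals put the median of all genes at 0.14 (log2) and the calls at 17209 higher and 11004 lower, and the median of the lignin list at 0.

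**Figure D3:**
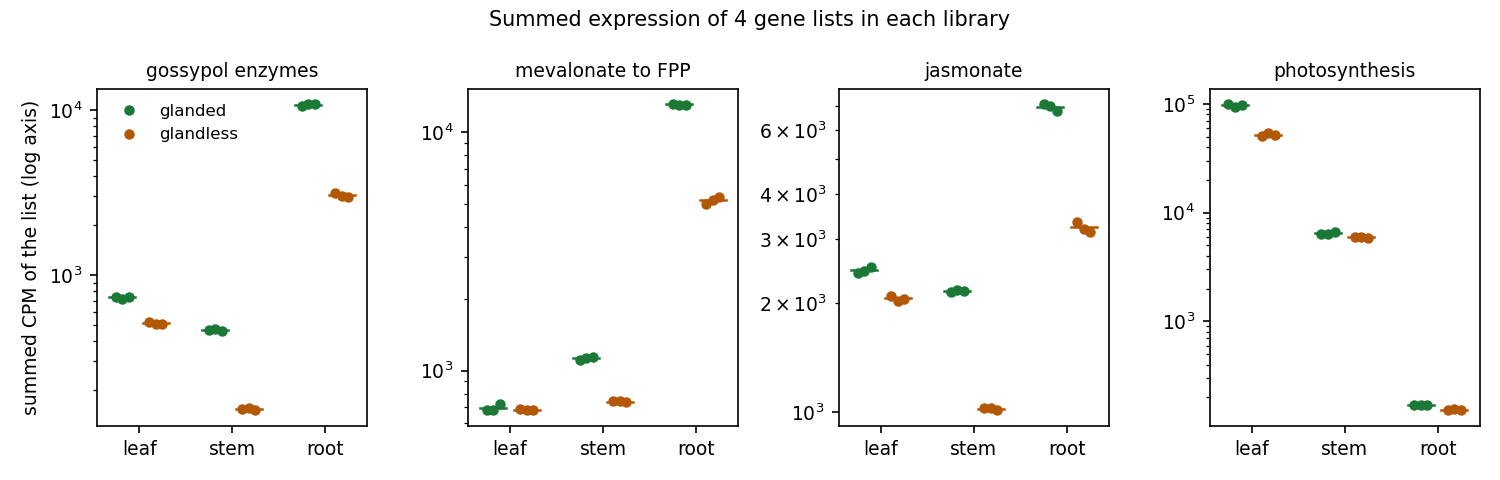
Summed CPM of 4 gene lists in each library on a log axis, by organ, with points for libraries and a bar for the mean of 3. Gossypol enzymes summed to 465 CPM in glanded and 154 CPM in glandless stem and to 10757 and 3048 CPM in root, and photosynthesis genes to 97025 and 51864 CPM in leaf.

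In root, where gossypol enzymes were expressed most, 34 of 57 members fell and 4 rose (35 and 5 adjusted over the list alone, median log2 fold change -1.33 or -1.30 with bounded values, camera adjusted p = 7.77e-31). The cadinene synthase LOC107920688 stood at 496 ± 28.8 CPM in glandless and 1852 ± 50.7 CPM in glanded libraries (log2 fold change -1.90 ± 0.062 (SE), edgeR adjusted p = 9.08e-29, n = 3 per line), and 15 of 19 cadinene synthases fell, led by LOC107925552 (chromosome A01, 115559161 to 115561640) (-3.96 ± 0.072) and LOC107928183 (-4.04 ± 0.078). CYP82D47 LOC107944158 changed by -1.53 ± 0.068 and CYP736A12 LOC107892025 by -2.02 ± 0.058. For the mevalonate pathway 25 of 45 members fell and 4 rose (27 and 4 adjusted over the list alone, median log2 fold change -0.83, camera adjusted p = 2.56e-28). Farnesyl diphosphate synthase LOC107905701 stood at -1.89 ± 0.055, HMG-CoA reductases LOC121203148 at -2.21 ± 0.059 and LOC107939227 at -0.82 ± 0.05, and HMG-CoA synthase LOC107929285 at -2.12 ± 0.06. Beside these groups, 31 genes with at least 150 counts in glandless leaf, stem and root each and at most 1 count in glanded leaf and stem together all had counts in glanded root, at a median of 8.45% of the glandless root level (interquartile range 7.11 to 10.4%). Of 25 genes chosen the same way with the lines exchanged, 2 had counts in glandless root, and the median was 0%.

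Jasmonate genes were lower in glandless root, where 47 of 85 members fell and 12 rose (49 and 14 adjusted over the list alone, median log2 fold change -0.48, camera adjusted p = 8.57e-17). The lipoxygenases LOC107919998 (-3.04 ± 0.057) and LOC107894336 (-5.37 ± 0.11) had the smallest p in that direction. In MYC-type transcription factors, some of which act in jasmonate signalling, 10 of 18 members fell and 1 rose (10 and 2 adjusted over the list alone, median log2 fold change -0.73 or -0.50 with bounded values, camera adjusted p = 0.000587). Their summed level was 1059 CPM in glandless and 1026 CPM in glanded root. MYC2 LOC107890614 stood at -1.35 ± 0.088 and LOC107950166 at -1.04 ± 0.072. The MYC2 genes on A12, LOC107946750, and D12, LOC107946831, changed by -0.48 ± 0.09 and -0.53 ± 0.10 in root, while their edgeR adjusted p was 0.555 and 0.795 in leaf and 0.784 and 0.126 in stem. Without glandless stem replicate 3, LOC107946831 in stem had an adjusted p of 0.0317. Lignin genes included laccase-14 LOC107959545 (-2.90 ± 0.06) and LOC107914066 (-2.96 ± 0.062), and 107 of 221 members fell and 27 rose (112 and 29 adjusted over the list alone, median log2 fold change -0.44 or -0.43 with bounded values, camera adjusted p = 1.36e-10). For flavonoid genes 29 of 84 members fell and 12 rose (29 and 14 adjusted over the list alone, median log2 fold change -0.14 or -0.13 with bounded values, camera adjusted p = 0.0102). Flavonoid 3'-monooxygenases LOC107963672 (-1.69 ± 0.056) and LOC107920158 (-1.55 ± 0.073) had the smallest p in that direction. Dirigent proteins were led by LOC107903450 (-2.02 ± 0.057) and LOC107903449 (-2.95 ± 0.12), and 23 of 71 members fell and 8 rose (26 and 10 adjusted over the list alone, median log2 fold change -0.37 or -0.34 with bounded values, camera adjusted p = 4.34e-05). In other terpene synthases 7 of 17 members fell and 0 rose (7 and 0 adjusted over the list alone, median log2 fold change -1.04 or -0.98 with bounded values, camera adjusted p = 0.000222). LOC107888718 (-2.43 ± 0.13) and LOC107892237 (-1.87 ± 0.10) had the smallest p in that direction. For dioxygenases and short-chain dehydrogenases 52 of 153 members fell and 28 rose (53 and 32 adjusted over the list alone, median log2 fold change -0.035, camera adjusted p = 0.00119). LOC107941627 (-2.96 ± 0.071) and LOC107941629 (-2.50 ± 0.076) had the smallest p in that direction.

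Secondary wall genes in root gave the count that 65 of 120 members fell and 5 rose (70 and 5 adjusted over the list alone, median log2 fold change -0.46 or -0.45 with bounded values, camera adjusted p = 6.97e-11). LOC107889975 (-1.0 ± 0.066) and LOC107924802 (-0.92 ± 0.062) had the smallest p in that direction. In root 25 of 40 fasciclin-like arabinogalactan proteins fell (median -0.48), as did 40 of the 80 other members (median -0.44). The root hair list, led by the kinases LOC107938246 (-1.17 ± 0.073) and LOC107958762 (-1.19 ± 0.08), showed that 17 of 47 members fell and 3 rose (17 and 3 adjusted over the list alone, median log2 fold change -0.08, camera adjusted p = 0.00515). For aquaporins 47 of 88 members fell and 14 rose (48 and 15 adjusted over the list alone, median log2 fold change -0.39, camera adjusted p = 5.7e-07, adjusted p = 0.118 with an estimated correlation). PIP2-2 LOC107889604 (-1.84 ± 0.077) and LOC107899648 (-1.77 ± 0.085) had the smallest p in that direction. Groups that rose were cyclins and histones, where 71 of 195 members rose and 5 fell (72 and 5 adjusted over the list alone, median log2 fold change 0.33, camera adjusted p = 5.7e-07, adjusted p = 0.0638 with an estimated correlation). H1-like histones LOC107912798 (1.47 ± 0.074) and LOC107913009 (1.27 ± 0.087) had the smallest p in that direction. Among ribosomal proteins 114 of 709 members rose and 11 fell (74 and 10 adjusted over the list alone, median log2 fold change 0.13, camera adjusted p = 0.000253, adjusted p = 0.331 with an estimated correlation). Their summed level was 13723 CPM in glandless root replicate 1, below the 13779 to 14097 CPM of glanded root, and 15601 and 16282 CPM in replicates 2 and 3. Without any single library the adjusted p stayed at 0.0111 or lower, the highest without glandless root replicate 3. LOC107909701 (3.56 ± 0.26) and LOC107900848 (0.54 ± 0.08) had the smallest p in that direction. LOC107909701 was among the 31 genes with at most 1 count in glanded leaf and stem together, and its glanded root level was 7.57% of the glandless one. In late embryogenesis abundant proteins and dehydrins 9 of 26 members rose and 5 fell (9 and 5 adjusted over the list alone, median log2 fold change 0.14 or 0.037 with bounded values, camera adjusted p = 0.0429, adjusted p = 0.277 with an estimated correlation). That call was lost without glandless root replicate 3 (adjusted p = 0.0782), glanded root replicates 1, 2 or 3 (0.0532, 0.0546 and 0.051) or glanded stem replicates 2 or 3 (0.0534 and 0.056). ERD10 LOC107917975 (1.45 ± 0.074) and LOC107896693 (0.95 ± 0.07) had the smallest p in that direction.

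Some lists did not pass in root, each given with its median log2 fold change and camera adjusted p. The methylerythritol phosphate pathway (-0.017, 0.08), photosynthesis genes (0, 0.516), endodermis genes (0, 0.156), the heat shock list (0.11, 0.101) and pathogenesis-related proteins (0, 0.258) were among these. Glutathione S-transferases (-0.0076, 0.878), lipid transfer and cuticle genes (0, 0.856), ABC and MATE transporters (-0.029, 0.216), WRKY genes (-0.043, 0.0929), ethylene-responsive factors (0, 0.257) and cytochrome P450 enzymes (0.047, 0.554) were among these. With each organ fitted alone, the methylerythritol phosphate pathway (adjusted p = 0.006), ethylene-responsive factors (0.0185) and WRKY genes (0.00999) passed in root, and transporters did so with DESeq2 (0.0335). Glutathione S-transferases were tested as higher against a negative median and mean. Cytochrome P450 enzymes (mean -0.021) and ethylene-responsive factors (mean -0.0016) were also tested as higher against a negative mean. The leading rises in root were the subtilase SBT3 LOC107902657 (chromosome D05, 18453053 to 18455305) (75.2-fold, with a counting interval of 20.5 to 626), heparanase-like 3 LOC107940072 (5.91 ± 0.40), BDA1-like LOC107895851 (63.4-fold, with a counting interval of 21.4 to 310), the epimerase LOC107912755 (5.80 ± 0.36) and acyl-CoA oxidase 3 LOC107908239 (52.9-fold, with a counting interval of 17.8 to 259). The leading falls were the cytoplasmic kinase LOC107934424 (chromosome D10, 64215913 to 64219103), at least 660-fold lower, TIC236 LOC107922603 (at least 280-fold), the splicing factor LOC107934420 (at least 247-fold), TIC32 LOC107941513 (at least 134-fold) and RGA3 LOC107934592 (1150-fold, with a counting interval of 393 to 5570). In all, 18042 genes were called, 7865 higher and 10177 lower, with 2667 and 3190 at 2-fold or more. Scaling by library totals put the median of all genes at 0.16 (log2) and the calls at 13945 higher and 7021 lower, and the medians of the root hair list at 0.078, of the dioxygenase list at 0.041 and of the flavonoid list at 0. The counts of these lists then became 16 lower and 10 higher, 46 lower and 42 higher, and 21 lower and 18 higher.

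Genes called in all 3 organs in one direction were compared next. The tubulin alpha-4 gene LOC107886968 (chromosome D02, 69067284 to 69069417) changed by -2.26 ± 0.054, -3.95 ± 0.058 and -3.13 ± 0.06 (log2, SE) in leaf, stem and root. Formate-tetrahydrofolate ligase LOC107939256 changed by 2.32 ± 0.089, 3.36 ± 0.11 and 2.35 ± 0.092. The SC35-like splicing factor LOC107934420 (chromosome D10, 64219544 to 64222710) had no counts in any glandless library. Lower in leaf, stem and root were also glutamate decarboxylase LOC107946304 (-2.38 ± 0.10 in leaf), PIP2-2 LOC107889604 (-5.28 ± 0.094), GDP-L-galactose phosphorylase LOC107903465 (-1.02 ± 0.046), cyclin-dependent kinase F-4 LOC107946808 (-1.34 ± 0.064), flavonol sulfotransferase-like LOC107902197 (-4.27 ± 0.093) and a galactosyltransferase, LOC107946586 (-2.09 ± 0.10). In all 1074 genes were higher and 2019 lower in the 3 organs, against 344 and 456 for independent lists, and at 2-fold or more 285 and 435 against 11.3 and 23.8. Many genes were called in opposite directions, 5210 in leaf and stem, 3789 in leaf and root and 2861 in stem and root. Independent lists would give 5280, 3670 and 3923 of these. Across the 59600 genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r of 0.269 between leaf and stem, 0.212 between leaf and root and 0.349 between stem and root, and Spearman's rho of 0.126, 0.0916 and 0.261. With library totals the count of genes called in all 3 organs in one direction became 4722, of which 3625 were higher and 1097 lower.

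The next comparison asked whether called genes lay on particular chromosomes more often than on the rest. Chromosome D05 held more called genes than the rest in leaf (44.1% of 3355 against 40.5%, one-sided Fisher's exact adjusted p = 0.000544), in stem (46.5% against 43.5%, adjusted p = 0.00924) and in root (33.5% against 30.1%, adjusted p = 0.000634). A03 did so in leaf (43.8% of 2009 against 40.6%, adjusted p = 0.0295), while A12 and D12 did not pass in any organ, with adjusted p from 0.507 up. Genes are not independent replicates, and leaving out single libraries gave from 1 to 3 such chromosomes in leaf and from 0 to 2 in stem, with 0 in stem without replicate 3 of either line's stem. D05 in stem had an adjusted p of 0.13 without glandless stem replicate 3, and 0.0591 and 0.0972 without glanded stem replicates 1 and 3. Among the 18 fits without 1 library, A03 in leaf passed without glandless leaf replicate 3 (0.00974), glandless stem replicate 2 (0.0485), glanded stem replicate 3 (0.045) or glandless root replicates 1 or 3 (0.0327 and 0.0439), and in the others it ranged from 0.0504 to 0.197. For D05 in leaf, stem and root the adjusted p was 0.108, 0.625 and 0.475 with library totals and 0.189, 0.11 and 0.0529 for changes of at least 2-fold, so these calls were lost in both. A03 in leaf was lost with library totals (0.244), without the filter (0.0813), with at least 20 counts in 3 libraries (0.0626), for changes of at least 2-fold (0.718) and with each organ fitted alone (0.601), and with genes called at an adjusted p under 0.01 its adjusted p was 0.11.

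More genes differed between organs than between lines. Chlorophyll a-b binding protein CP29.3 LOC107900536 (chromosome D06, 59918169 to 59920363) averaged 110.5 ± 37.3 CPM in leaf (SD, n = 6) with no counts in stem or root, and YABBY 5 LOC107962606, a regulator of leaf polarity, averaged 35.25 ± 12.4 CPM in leaf alone. Further leaf-enriched genes were BDA1-like LOC107936438 (138 CPM), dehydrodolichyl diphosphate synthase LOC107891622 (255 CPM) and MLO-like LOC121218590 (28.4 CPM). In stem the xyloglucan endotransglucosylases LOC107902739 (214.5 ± 6.15 CPM) and LOC107960771 (284 ± 33.8 CPM), the knotted-1-like homeobox gene LOC107930537 (181.5 ± 36.7 CPM), a GDSL lipase, LOC107907357 (39.3 CPM), and mini zinc finger 2-like LOC107940763 (30.7 CPM) stood out. In root the nitrate and peptide transporter family gene LOC107938537 reached 649.8 ± 113 CPM, iron transporter 1 LOC107897476 reached 195 ± 20 CPM, and peroxidase 27 LOC107908295, a dioxygenase, LOC107938040, and carotenoid cleavage dioxygenase 8 LOC107901528 reached 111, 217 and 155 CPM. Of the fixed lists, 134 of 148 photosynthesis genes were leaf-enriched (two-sided Fisher's exact adjusted p = 1.61e-92), 72 of 120 secondary wall genes stem-enriched (9.64e-39), and 38 of 57 gossypol enzymes (3.85e-18) and 43 of 65 endodermis genes (3.28e-20) root-enriched. In all 8769 genes were leaf-enriched, 6201 stem-enriched and 8709 root-enriched, and edgeR called 46289 genes between stem and leaf (24508 higher in stem), 49829 between root and leaf (26280 higher in root) and 45949 between root and stem (20839 higher in root). With library totals the stem and leaf comparison gave 30855 higher and 16098 lower.

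The last comparison asked whether the difference between lines itself differed between organs. For gossypol enzymes the line difference in root minus that in stem had a median of 3.12 (log2, camera adjusted p = 5.54e-12), and CYP736A12 LOC107892025 differed by -6.50 between stem and leaf (edgeR adjusted p = 7.03e-24). The summed level of gossypol enzymes did not show a larger relative fall in stem. It was 154 CPM in glandless and 465 CPM in glanded stem, and 3048 and 10757 CPM in root. For the mevalonate list the line difference in root minus that in leaf had a median of -1.44 (camera adjusted p = 8.13e-19), and for photosynthesis genes stem minus leaf gave 0.96 (1.9e-42). Jasmonate genes differed by -1.19 between stem and leaf (2.87e-10), and WRKY genes by 0.60 between root and stem (3.62e-08). In all 22870 genes differed between stem and leaf (11325 higher, 11545 lower), 17937 between root and leaf (8189 higher, 9748 lower) and 16379 between root and stem (8543 higher, 7836 lower). Scaling by library totals changed the first of these splits to 7480 higher and 16155 lower and the second to 6128 higher and 13740 lower.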

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

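In the weighing that follows, the test on a second set of genes, the test of own expression and the test of stem tissue were set down before their results were seen, and the other tests of the 3 patterns were chosen after. The line difference itself differed between organs for 22870 genes between stem and leaf, 17937 between root and leaf and 16379 between root and stem (edgeR interaction contrasts). In 40 shuffles that included the real grouping, 1 grouping, the real one, gave as many, and the highest other values were 5563, 4425 and 6058. The shuffles exchanged line labels within organs, which mixes the lines within groups and raises the spread there. They therefore do not decide whether these counts exceed chance.

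For 21 lists the line difference differed between organs, given here as the median of the contrast with the smallest camera p. Root minus stem gave 3.12 for gossypol enzymes, 0.33 for pathogenesis-related proteins, 0.55 for glutathione S-transferases, 0.60 for WRKY genes and 0.83 for the dioxygenase group. The same contrast gave 0.27 for the methylerythritol phosphate pathway, 0.51 for ethylene-responsive factors, 0.74 for dirigent proteins, -0.26 for secondary wall genes and 0.41 for endodermis genes. It gave 0.26 for aquaporins, 0.83 for late embryogenesis abundant proteins and 0.46 for cytochrome P450 enzymes. Root minus leaf gave -1.44 for the mevalonate pathway and -0.64 for lignin genes. Stem minus leaf gave -1.19 for jasmonate genes, -0.64 for flavonoid genes, 0.96 for photosynthesis genes, -0.44 for the root hair list, -0.25 for ribosomal proteins and -0.25 for the heat shock list. With an estimated correlation the adjusted p was 0.081 for the root hair list, 0.524 for ribosomal proteins and 0.323 for aquaporins, and the other 18 stayed under the threshold.

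Of 108 named genes, 94 had a line difference that differed between organs in the edgeR interaction test, given here as the largest log2 difference among the contrasts that passed. Most were named for a large or clear line difference in a single organ of these data, so this share was partly built in. Of all tested genes, 38.4% were called between stem and leaf, 30.1% between root and leaf and 27.5% between root and stem. Where a gene had no counts in a group the fitted difference depends on the prior count and is no bound. LOC107909701 and LOC107956040 belong to the 31 genes whose reads in glanded root are of open source, at 7.57% and 11.9% of the glandless root level, and LOC107902249 had 0.0964 CPM in glanded and 0.906 CPM in glandless root, so their differences from root are open too. Stem minus leaf came first. LOC121220185 had -10.95, LOC121220187 -11.78, LOC107942101 13.16, LOC107896471 -1.09, LOC121217457 -3.27, LOC107956740 9.91, LOC107953740 -14.14, LOC107892025 -6.50 and LOC107937536 -6.55. LOC107946991 had -3.81, LOC107918523 -8.17, LOC107926260 -12.16, LOC107903448 -10.38, LOC107916413 -3.06, LOC107915240 -3.47, LOC107959545 -11.42, LOC107927759 -2.07 and LOC107938246 -1.54. LOC107946476 had -1.95, LOC121232133 -3.78, LOC107898953 -6.32, LOC107891002 -5.11, LOC107889738 -8.72, LOC107897348 -3.62, LOC107940004 -2.79, LOC107912798 0.77 and LOC107913009 0.38. LOC107950283 had -3.05, LOC121203008 -12.30, LOC107942044 -7.08, LOC121212611 -6.53, LOC107912755 8.45, LOC107925552 -10.61, LOC107928183 -14.34, LOC107920158 -5.74 and LOC107958762 -0.44. LOC107917975 had -3.08, LOC107896693 1.81, LOC107920688 -7.10, LOC107944158 -7.74, LOC107886968 -1.69, LOC107939256 1.03, LOC107903465 -0.21, LOC107946808 -0.29 and LOC107902197 0.47. LOC107946586 had 0.50. Root minus leaf was next. LOC107913466 had -15.26, LOC107950200 -12.11, LOC107930932 -2.96, LOC107898896 -1.44, LOC107897631 1.52, LOC107896517 1.43, LOC107954741 3.04, LOC107914060 3.52 and LOC107954983 2.06. LOC107889457 had 2.08, LOC107909701 -7.23, LOC107907538 -3.08, LOC107889604 3.44, LOC107891130 1.96, LOC107939227 1.57, LOC107946184 1.35, LOC107889975 1.89 and LOC107940072 6.74. LOC107934592 had -6.60, LOC121203148 -2.73, LOC107929285 -2.33, LOC107919998 -4.27, LOC107890614 -2.58, LOC107899648 -1.25, LOC107905701 -1.97 and LOC107946831 -0.48. Root minus stem was last. LOC107902249 had -8.00, LOC107956040 -7.72, LOC121225257 12.20, LOC107932362 10.49, LOC107903450 4.28, LOC107914066 6.46, LOC107963672 5.58, LOC107908518 7.82 and LOC107926521 1.80. LOC107940910 had 2.68, LOC121203613 4.17, LOC107922715 2.93, LOC107888718 5.23, LOC107892237 6.27, LOC107903449 5.26, LOC107894336 -7.13, LOC107950166 -0.65 and LOC107924802 0.68. LOC107900848 had 0.33, LOC107941629 5.43, LOC107946750 -0.52 and LOC107946304 1.70.

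In glanded root, all 31 genes with at least 150 counts in glandless leaf, stem and root each and at most 1 in glanded leaf and stem together had reads, at a median of 8.45% of the glandless root level, with library medians of 9.16%, 8.60% and 7.69%. The tables argue against reads passing from leaf into root libraries at that share, since photosynthesis reads in root were only 0.323% of their share in leaf. These reads cannot show passing between root libraries, as they took 0.0164% of glanded and 0.0166% of glandless root counts. The tables also argue against RNA with the profile of the sampled glandless root at that share, since 9 of 37302 genes with at least 150 glandless root counts lay below 2.11%, among them subtilase SBT3 LOC107902657 with 2 counts against 163. Some glandless root RNA may be present, as a second set of only 4 genes stood at a median of 11.74% (interquartile range 11.12 to 12.75%). Own expression of the 31 genes stays open. In 852 of 1000 random draws from 1231 other genes lower in glanded root, the quartile ratio was wider than theirs of 1.46. That test compares the spread of the shares and not their level, so it cannot decide. Just 2 of 25 genes of the reverse kind had counts in glandless root (median 0%), so such reads in root were not general to both lines. Those 25 are other genes in the other line, so they do not decide on own expression of the 31. A source that lifts other genes high in glandless root stays open too, with 2 of 37271 such genes under 1% in glanded root against 35 of 35876 in the reverse direction, and a difference between the lines themselves was not tested.

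In stem, genes enriched in root were lower in glandless plants, gossypol enzymes among them. Whole root tissue as sampled is argued against, since 8 of the 50 most abundant root-enriched genes lay below 1.23% of their root level in glanded stem, down to 0.0651% for the aquaporin LOC107932296, where the gossypol enzymes would need 4.94%. Root tissue of another zone may still contribute and cannot be told apart, as the 50 genes had a median excess of 2.149% (interquartile range 1.342 to 4.94%), while endodermis genes, 43 of 65 root-enriched, went both ways, 21 lower and 10 higher in glandless stem, with a summed level of 526 CPM there against 236 CPM in glanded stem. A defence response induced in the glanded stems cannot be told apart from the line either. Of 85 jasmonate genes 51 were lower in glandless stem, but every glanded stem library shares line and sampling. Among the 85, 42 were root-enriched, so their fall is not separate from that of root-enriched genes. The line itself stays open and untested.

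In leaf, photosynthesis genes were lower in glandless plants. Stem tissue in the glandless leaf sample is argued against, since the 50 most abundant stem-enriched genes stood at a median of 7.296% of their stem level (interquartile range 2.044 to 15.08%), against 5.689% in glanded leaf and 49.5% needed. Scaling cannot be told apart as a part of the size, as the median was -0.6638 with library totals and -0.99 with TMM, negative under both. Younger leaves in the glandless sample could not be excluded, as the cyclin and histone list gave an adjusted p of 0.357 in leaf. A difference between the lines in leaf development stays open and untested.

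Other groupings of the samples were counted for the remaining results, and in each of them 1 grouping, the real one, gave a value as large. Within an organ, 3 libraries against 3 allow only 10 splits, too few for a share under 0.05. Fits of each organ alone gave 21052 genes in leaf, 27639 in stem and 18152 in root, with 0 as the highest other split in each. They gave 10, 18 and 18 gene lists, against up to 9, 15 and 11 in other splits. Every other split still sets 2 libraries of one line and 1 of the other against the reverse, so part of the line difference remains in it. Each organ gave 1 chromosome, with 0 as the highest other, which was fixed because no other split called a gene. Called in all 3 organs were 2760 genes, with 0 as the highest other of 100 groupings that included the real one. As no other split within an organ called a gene, a grouping that used such a split had to give 0, so this count decides nothing about chance. Over 40 shuffles of organs the real grouping gave 46289 genes between stem and leaf (highest other 23764), 49829 between root and leaf (16252) and 45949 between root and stem (86). It gave 8769 leaf-enriched, 6201 stem-enriched and 8709 root-enriched genes, where the highest others were 67, 4 and 11. Shuffles that mix organs within groups raise the spread there and so lower their own counts. They therefore do not decide about chance.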

How the results depend on the processing

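The alternative that subtracts the estimated glandless share from the glanded root counts was chosen after the data were seen, and all others were planned. Of 365 values of gene counts under the alternatives, 353 stayed within 1.5 times the reported count, as did 87 of 87 counts of lists and 51 of 87 counts of chromosomes. Named genes kept direction and side of the threshold in 5246 of 5276 cases under the alternatives, with 17 weaker, 2 stronger and 11 reversed, and lists in 2203 of 2340, with 38 weaker, 62 stronger and 37 reversed. Every reversed value belonged to a result that had not passed the threshold. Of the lists called, late embryogenesis abundant proteins in root were lost in 12 of 30 alternatives, among them library totals (adjusted p = 0.0959), no filter (0.139), the replicate block (0.102), limma (0.058) and the estimated correlation (0.277), and 6 fits without 1 library. Those were without glandless root replicate 3 (0.0782), glanded root replicates 1, 2 and 3 (0.0532, 0.0546 and 0.051) and glanded stem replicates 2 and 3 (0.0534 and 0.056). The heat shock list in stem was lost in 8, up to 0.232 with each organ fitted alone, and without glanded stem replicates 1 and 3 (0.054 and 0.068). Ethylene-responsive factors in stem were lost in 4, up to 0.219 with DESeq2, and late embryogenesis abundant proteins in stem in 3, up to 0.139 with an estimated correlation. The plastid pathway in leaf was lost with library totals (0.0775). Of the 17 weaker cases of genes, 7 were CYP82D47 LOC107944158 in leaf, lost among others with each organ fitted alone (0.157), limma (0.0567), and without glanded leaf replicate 2 (0.359) or glandless leaf replicates 1 or 3 (0.166 and 0.0569). Of 62 gains 26 came with fry, which does not compare a list with other genes. Each organ fitted alone gave gains in leaf for ethylene-responsive factors (0.000362), flavonoid genes (0.0103) and late embryogenesis abundant proteins (0.00876), in stem for cytochrome P450 enzymes (0.03), and in root for the plastid pathway (0.006), ethylene-responsive factors (0.0185) and WRKY genes (0.00999). DESeq2 gave them in root for the plastid pathway (0.0222), ethylene-responsive factors (0.0218) and transporters (0.0335). Library totals gave them in leaf for ethylene-responsive factors (0.000674), flavonoid genes (0.0454) and gossypol enzymes (0.0352), and at least 20 counts for the first and second of these (0.0227 and 0.0376). MYC-type factors in stem and glutathione S-transferases in leaf passed with the replicate block (0.0423 and 0.0483), without the filter (0.0211 and 0.0447) and with limma (0.0363 and 0.0173). Single omitted libraries gave gains for lists in leaf: ethylene-responsive factors without glandless or glanded replicate 2 (0.0484 and 0.0445), flavonoid genes without glandless replicate 1 (0.0497), and glutathione S-transferases (0.0298 to 0.0495) without glandless leaf replicates 1 or 3, glanded leaf replicate 1, glandless stem replicates 2 or 3, glanded stem replicate 1 or glandless root replicate 2. They also gave gains for the heat shock list in root without glandless root replicate 1 (0.0473) and MYC-type factors in stem without glanded root replicates 2 and 3 (0.0487 and 0.0495). Library totals gave 4722 genes called in all 3 organs, and 0, 2 and 0 chromosomes in leaf, stem and root. A minimum change of 2-fold, by its construction, left 8834 genes in leaf, 9498 in stem, 5857 in root, 26139 between stem and leaf, 31985 between root and leaf and 25482 between root and stem. It left 10946, 8799 and 7886 genes for the line difference between stem and leaf, root and leaf and root and stem, 720 genes in all 3 organs, and 1, 0 and 0 chromosomes. limma on log2(FPKM + 1) gave 3402 stem-enriched genes and 2 chromosomes in root. Without a filter beyond 1 count there was 1 chromosome in leaf and 2 in stem, and with each organ fitted alone 1 in leaf. With 0.01 as the limit for genes and chromosomes alike there was 1 in leaf and 0 in stem. D05 in stem then had an adjusted p of 0.0128 (one-sided Fisher's exact test), under the 0.05 used elsewhere. The share subtraction gave 2 chromosomes in stem, 20040 genes in root and 3209 in all 3 organs. For library totals, limma, the filter, the organ fits and the subtraction the cause was not tested.

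Replicate numbers did not pair libraries of the lines within an organ, as correlations of residuals with the same number ran from -0.0714 to 0.0773. Within a line they ran from -0.0243 to 0.275 with the same number and from -0.217 to 0.136 with different numbers. A source shared by organs of the same number within a line is therefore not excluded. With a block for replicate numbers within an organ the counts were 23556 in leaf, 25336 in stem, 17365 in root and 2975 in all 3 organs, with 2 chromosomes in stem. Leaving out 1 library at a time gave from 21974 to 24941 genes in leaf, from 23072 to 26719 in stem and from 15371 to 18877 in root. It gave from 1 to 3 chromosomes in leaf and from 0 to 2 in stem, with 0 in stem without replicate 3 of glandless or of glanded stem.

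MYC2 LOC107946750 in leaf stood at 0.26 (adjusted p = 0.00755) and LOC107946831 at 0.28 (0.025) on the log2 scale with library totals, both past the threshold in the other direction from values that had not passed. In stem LOC107946750 stood at -0.0042 with each organ fitted alone, -0.0022 with limma and from -0.035 to 0.097 over all fits without 1 library. Cadinene synthase LOC107920688 in leaf ran from -0.49 without glandless leaf replicate 2 to 0.50 without glanded leaf replicate 1, and stood at -0.30 without glanded leaf replicate 3. The camera adjusted p of lists whose direction reversed with library totals was 0.0443 for dirigent proteins, 0.784 for endodermis genes, pathogenesis-related proteins and cytochrome P450 enzymes, 0.561 for WRKY genes and 0.728 for the dioxygenase group in leaf. It was 0.559 for photosynthesis genes in stem, and 0.531 for these and 0.527 for cuticle genes in root. Without the filter it was 0.7 for dirigent proteins in leaf and 0.986 for photosynthesis genes in stem. Organ fits gave 0.882 for WRKY genes in leaf, 0.54 for endodermis genes in stem and 0.839 for cytochrome P450 enzymes in root. The block gave 0.938 for dirigent proteins in leaf and 0.984 for glutathione S-transferases in root. fry gave 0.335 for dirigent proteins and 0.000202 for WRKY genes in leaf, and in root 0.323 for glutathione S-transferases, 0.00242 for cuticle genes and 5.9e-09 for cytochrome P450 enzymes. DESeq2 gave 0.75 for other terpene synthases and 0.765 for WRKY genes in leaf, 0.462 for endodermis genes in stem and 0.313 for cytochrome P450 enzymes in root. Over all fits without 1 library, the adjusted p ran from 0.84 to 1 for dirigent proteins in leaf, from 0.728 to 0.979 for photosynthesis genes in stem and from 0.609 to 0.99 for glutathione S-transferases in root. The cause of these reversals was not tested.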

Other observations

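Among MYC-type factors, 2 genes had no counts in any of the 9 glandless libraries, and both were chosen after their values were seen. MYC1 LOC107947206 on A12 had 196 counts over the 9 glanded libraries, and MYC2-like LOC121224354 on D12 had 63. Of all tested genes, 88 had no counts in any glandless library and counts in all 9 glanded libraries, and 6 showed the reverse. The 6 leave out genes such as the 31 with reads of open source in glanded root. With root left aside, 55 genes had at least 150 counts in glandless leaf and stem each and at most 1 in glanded leaf and stem together, and 40 showed the reverse. A sequence difference from the reference was not tested as a reason for counts of 0.

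Annotated gene families with at least 20 members, 251 in all, were tested with camera after the data were seen. In leaf 30 families passed, of which 1 held with an estimated correlation, in stem 48 and 13, and in root 15 and 2. Those that held in leaf and root and the 5 with the smallest adjusted p in stem are given. SPX domain genes, which sense phosphate status, rose in leaf (16 of 31 higher and 4 lower, adjusted p = 0.000158, or 0.0257 with an estimated correlation) and fell in stem (21 lower and 2 higher, adjusted p = 4.49e-09, or 0.00104). In stem the Zim family of TIFY proteins (26 of 34 lower and 2 higher, adjusted p = 2.18e-20, or 0.0107) and the WRKY family (113 of 210 lower and 32 higher, adjusted p = 5.64e-08, or 0.00104) also fell. Epimerases fell in stem (41 of 82 lower and 5 higher, adjusted p = 7.55e-08, or 0.00667), and the POX family of homeodomain-associated genes rose (30 of 44 higher and 5 lower, adjusted p = 2.32e-06, or 0.0106). In root, GRAS regulators rose (65 of 142 higher and 15 lower, adjusted p = 6.01e-07, or 0.000857), as did RPE65-type carotenoid oxygenases (14 of 28 higher and 0 lower, adjusted p = 6.74e-05, or 0.0172).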
